A study of Mus musculus with 4 samples.

How the data were processed

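RNA was measured in dorsal root ganglia of adult mice, the clusters of sensory neuron cell bodies beside the spinal cord, either without injury or 72 hours after a crush injury of the sciatic nerve. Per the labels' protocols, bulk libraries were made with a nanopore direct RNA sequencing kit from RNA of the whole lysate of wild-type CD-1 mice. RiboTag libraries were made with a nanopore cDNA-PCR barcoding kit from RNA that came down with an anti-HA antibody in mice that carry an HA-tagged ribosomal protein (Rpl22) switched on by Advillin-Cre, a driver active in sensory neurons. Library kit, strain, genotype and immunoprecipitation therefore changed together between bulk and RiboTag RNA and cannot be told apart.

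The processed data were 4 tables, 1 per group, each listing the same 116912 mouse transcript identifiers. Per the file headers, each table held 3 numbered columns of estimated counts (reads assigned to a transcript, which need not be whole) and 3 of TPM, as deposited by the authors. Per the submitters' processing notes, minimap2 and Salmon were used with the builds GRCm39 and mm39. Their versions and settings, the transcript annotation and the making of the 3 columns are not given in the sources used here. In every column the deposited TPM was the estimated count multiplied by a constant, to within 0.0499% for values of 1 read or more, so no transcript length entered it and the values are reads scaled to a common total.

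The 3 columns of a library were not treated as replicates. The labels give 1 sample per group. Column totals within a library spanned 0.0833% to 0.203% of their mean, and over the 4 libraries they differed less than Poisson counting would give (chi-square 1.89 on 8 degrees of freedom, lower-tail p = 0.0159). Among transcripts with a mean of 20 or more reads, 15.9% (uninjured bulk), 15.3% (injured bulk), 6.78% (uninjured RiboTag) and 7.01% (injured RiboTag) differed between columns by a chi-square test at 0.001. The remainder had a mean chi-square per degree of freedom of 1.09 to 1.19, close to counting noise. Leaving out the others by the same test by itself lowers this value. Over all transcripts with 20 or more reads the mean was 9.96, 10.1, 3.52 and 4.20 in the same order. The median chi-square was 1.22 to 1.46 times that expected from counting. The columns of each library were averaged and counted as 1 sample, so no p-value between conditions is given. All intervals cover counting error only, not the spread between animals. They take the mean of the columns as a single count, and are wider than they would be if the columns held separate reads. A transcript is called steady below where its columns agreed by that chi-square test in every library compared. This definition was made after the data were examined.

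The mean depth per column was 592935 estimated reads for uninjured bulk, 529332 for injured bulk, 207597 for uninjured RiboTag and 79334 for injured RiboTag RNA. A count of 0 allows up to 3 reads, which is 5.06, 5.67, 14.5 and 37.8 on the TPM scale in the same order. These are nanopore reads without molecular identifiers, so reads of the PCR-amplified RiboTag libraries need not be independent molecules.

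Mean counts were scaled by the library total. The log2 ratio of 2 libraries was taken after adding 0.5 read to each count, and an exact conditional binomial 95% interval of the ratio was computed from counts rounded to whole numbers. Transcripts entered with 20 or more reads summed over the 2 libraries, and were counted as higher or lower at a ratio of 2-fold or more with an interval that excluded no change. The change of the RiboTag to bulk ratio with injury was the difference of the log2 changes in the 2 assays, with a normal 95% interval from the 4 counts, for transcripts with 20 or more reads in all and 5 or more in each assay. For a background in the same form, single columns were compared by this rule, in the 9 pairs between 2 libraries and the 3 pairs within each library. Lists of transcripts were set against 10000 random lists matched on mean expression in 10 classes. On simulated counts for the bulk injury comparison (7779 transcripts tested, 200 changed), the counting rule recovered 99.0% of 3-fold and 100% of 6-fold changes with 1 false call. For the RiboTag injury comparison (1855 tested) it recovered 98.0% and 100% with 0 false calls. The simulated reads had no ambiguous assignment.

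The comparisons, their rules, the naming rule and most alternatives were fixed before the data were examined. Alternatives added afterwards were the sum of the columns, steady transcripts only, columns that do not overlap, and totals without a dominant pair of RiboTag transcripts. The main unit planned was the gene, with transcripts summed, and the transcript was used in its place for the reason that follows. For each comparison, the rule named the 10 transcripts with the highest and the 10 with the lowest ratio among those counted as higher or lower with 50 or more reads. None of the 116912 transcript identifiers could be paired with a gene symbol from the tables used here, so sums per gene, the part of the naming rule that rests on gene annotation, the 23 fixed gene lists (cell type markers included) and a scaling without mitochondrial genes were not analysed here. Transcripts are given by identifier, at most 2 per direction and comparison, with no gene name and no coordinates. A transcript at 0 in a whole library is given as a bound against 3 reads in that library. Alternatives were TMM scaling (edgeR 4.0.16), the deposited TPM, other read minimums and pseudocounts, leaving out each column, and fits of edgeR's quasi-likelihood test and DESeq2 1.42.0 to the columns as if they were replicates. The factors for TMM scaling were computed over bulk and RiboTag libraries together. The edgeR fits used TMM factors computed within the columns compared. The plan named edgeR's test as the main one if the tables held replicate columns, and because the columns were judged to be 1 sample the descriptive rule was kept as the main one. Those fits measure only the spread between columns, and they count a transcript at adjusted p of 0.05 with no fold threshold. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3 were used.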

Results

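RNA of whole dorsal root ganglia (bulk RNA) and RNA bound to tagged ribosomes of sensory neurons (RiboTag RNA) was sequenced without injury and 72 hours after sciatic nerve injury. There was 1 sample in each of the 4 groups, so no difference below has a check against other animals. The bulk libraries held 592935 and 529332 reads per column without and with injury. The RiboTag libraries held 207597 and 79334. At least 1 column gave a value above 0 for 22148 transcripts in uninjured bulk, 21093 in injured bulk, 18565 in uninjured RiboTag and 13793 in injured RiboTag RNA.

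RiboTag RNA was dominated by a pair of transcripts that were rare in bulk RNA. ENSMUST00000217116.2 and a transcript listed 3 places before it together took 31.2% of reads in uninjured RiboTag RNA (exact binomial 95% interval 31.0% to 31.4%) and 40.9% after injury (40.6% to 41.3%). In bulk RNA the pair took 0.0189% (0.0156% to 0.0227%) and 0.0191% (0.0155% to 0.0232%). The reads of the pair were shared almost evenly between its members in RiboTag RNA, with 32868 and 31858 reads without injury. In each bulk column all of them went to a single member. The top 2 transcripts of bulk RNA took only 3.26% and 2.97% of reads. Between the RiboTag libraries the reads of the pair fell 1.99-fold and all other reads fell 3.05-fold. The gene of the pair is not named here, and whether its reads came from cellular transcripts, from the tagged construct or from amplification during library preparation was not tested.

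**Figure D1:**
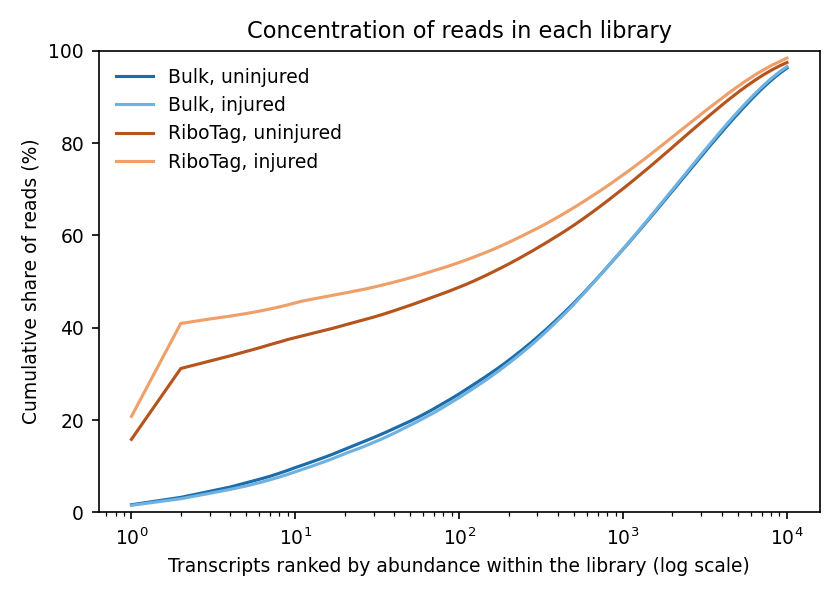
Cumulative share of reads (y axis, %) over transcripts ranked by abundance within each library (x axis, log scale), 1 line per library. The first 2 transcripts hold 31.2% and 40.9% of the RiboTag reads and 3.26% and 2.97% of the bulk reads.

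The first comparison asked which transcripts nerve injury changed in the whole ganglion. Of 7739 transcripts with 20 or more reads, 403 were counted as higher and 352 as lower after injury, and the median log2 change was 0.00. Single columns compared by the same rule gave 1209 to 1301 calls between the bulk libraries, 1077 to 1138 within the uninjured library and 956 to 991 within the injured one. Among 5979 steady transcripts, 97 were higher (median log2 change 1.51) and 41 lower (median -1.47). With counts of 0 set to 3 reads the medians were 1.55 and -1.55.

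Of the 20 named bulk transcripts, 17 had a counterpart within 10 places in the list that moved the opposite way by a like amount. ENSMUST00000082424.12 had 0 reads in each uninjured column and 164 to 190 in the injured columns, at least 64.5-fold higher. ENSMUST00000159216.10, listed 2 places away, had 187 to 227 reads without injury and 0 after it, at least 60.5-fold lower. The reads of these transcripts summed to 203.2 and 172.8, a log2 ratio of -0.07 relative to library totals. ENSMUST00000111343.2 was at least 47.7-fold higher, with injured columns ranging from 0 to 208 reads, and together with a transcript 2 places away its log2 ratio was -0.08. ENSMUST00000047104.15 was at least 104-fold lower, and together with the transcript 1 place away its reads were 1128.8 and 1008.3, a log2 ratio of 0.00. Its uninjured columns ranged from 0 to 1048 reads, and without the third column both libraries lay under 3 reads, so it had no value.

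**Figure D2:**
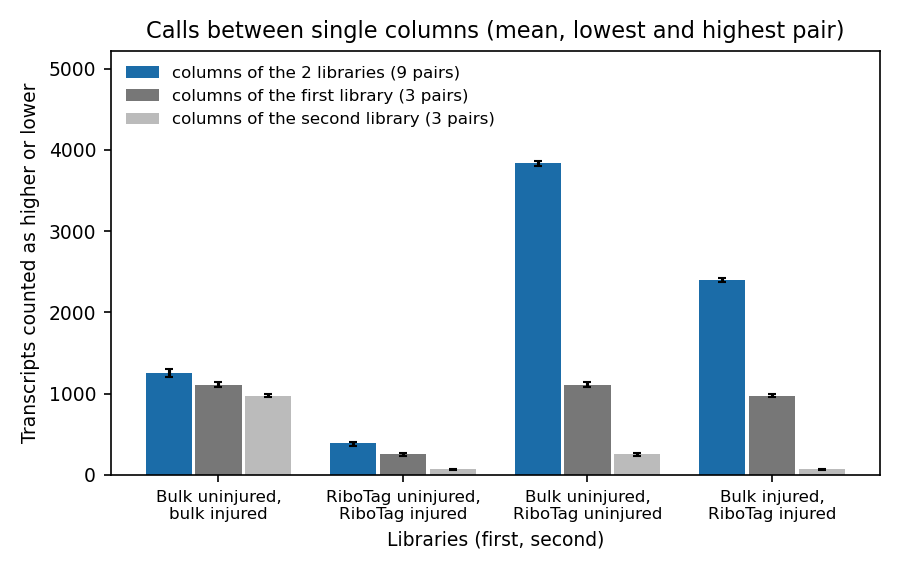
Transcripts counted as higher or lower (y axis) when single columns are compared, for pairs of libraries (x axis): columns of the 2 libraries (blue, mean of 9 pairs) and columns within the first (dark grey) and second library (light grey, mean of 3 pairs each), with lines from the lowest to the highest pair. In bulk RNA 1209 to 1301 calls between libraries stand beside 956 to 1138 within a library.

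The second comparison asked which ribosome-bound neuronal transcripts changed with injury. Of 1866 transcripts with 20 or more RiboTag reads, 55 were higher and 150 lower after injury, with a median log2 change of -0.21. Single columns gave 359 to 409 calls between the RiboTag libraries and at most 270 within either. Leaving the dominant pair out of the totals moved the median to 0.01 and the counts to 89 higher and 85 lower. TMM scaling, with factors computed over bulk and RiboTag libraries together, moved the median the other way, to -0.32, with 46 higher and 202 lower. A pseudocount of 5, which weighs more in the shallower injured library, gave 60 higher and 57 lower (median 0.13), no read minimum gave 239 and 202 (median 0.03), and a minimum of 50 reads gave 15 and 71 (median -0.24). With the columns fitted as if replicates, edgeR called 77 higher and 84 lower and DESeq2 68 and 66. Those fits had no fold threshold, so their counts are not under the same rule. The excess of lower calls depended on the settings. Among 1655 steady transcripts, 38 were higher (median log2 change 1.42) and 107 lower (median -1.45, or -1.54 with counts of 0 set to 3 reads).

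ENSMUST00000041500.8, a steady transcript with no opposite neighbour, was higher after injury in both assays. It had 19.7 reads in uninjured and 35.3 in injured RiboTag RNA, a log2 ratio of 2.22 (95% counting interval 1.36 to 3.07), with columns of 12 to 29 and 26 to 42 reads. In bulk RNA it had 158.7 and 303.0 reads, a log2 ratio of 1.09 (0.81 to 1.38). ENSMUST00000028300.6, also steady in RiboTag RNA, had 53.8 to 69.6 reads in uninjured columns and 0 after injury, at least 7.69-fold lower relative to library totals. Among transcripts with 50 or more reads, those with the highest and lowest RiboTag change were not steady. ENSMUST00000105616.10 had a log2 ratio of 3.07 (2.46 to 3.77) with injured columns from 0 to 175.5 reads, and summed with its neighbour the log2 ratio was -0.21. ENSMUST00000218813.2 was at least 7.91-fold lower, and its sum with a transcript 4 places away had a log2 ratio of -0.33.

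The third comparison set RiboTag against bulk RNA, which the series title frames as ribosome association. Without injury, 894 of 6174 transcripts were higher in RiboTag RNA and 2723 lower, with a median log2 ratio of -0.98. After injury, 388 of 5045 were higher and 1814 lower, with a median of -1.25. The median after injury turned to 0.18 with a pseudocount of 5 (404 higher, 753 lower) and to 0.08 with no read minimum (1361 higher, 1814 lower), and was -1.68 with a minimum of 50 reads (173 higher, 1301 lower). Without injury no read minimum gave 2166 higher and 3194 lower (median -0.36), a pseudocount of 5 gave 911 and 1848 (median -0.39) and a minimum of 50 reads 398 and 1529 (median -1.22). With the columns fitted as if replicates and no fold threshold, edgeR called 1416 higher and 1749 lower without injury and 723 and 1251 after it. With the column number as a block these were 1152 and 1098, and 407 and 413, without the excess of lower calls. Leaving the dominant pair out of the totals moved the medians to -0.45 and -0.49 and the counts to 1271 higher and 1955 lower without injury, and to 679 higher and 892 lower after it. Of 4687 transcripts measured in both states, 312 were higher in both and 1516 lower in both. Independent lists would share 42.5 and 838 transcripts, and 8 were called in opposite directions.

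Named transcripts separated the assays by large margins. ENSMUST00000217116.2 was 2328-fold higher in RiboTag RNA without injury (log2 ratio 11.17, interval 10.74 to 11.68) and 2889-fold higher after it (log2 ratio 11.48, interval 11.03 to 12). Its bulk columns alternated between 0 and all reads of the dominant pair, and the pair summed had a log2 ratio of 10.68 without injury. ENSMUST00000154078.3 had 648.6 reads in uninjured and 193.1 in injured RiboTag RNA and 0 in bulk RNA, at least 617-fold and 429-fold higher, though its injured RiboTag columns ranged from 0 to 364.5 reads. ENSMUST00000118875.8 had 1111 and 1119 reads in bulk RNA and 0 in RiboTag RNA, at least 130-fold and 55.9-fold lower. ENSMUST00000108702.8 was at least 106-fold lower without injury. ENSMUST00000019649.4, with 2502 and 2328 bulk reads, had 17.9 RiboTag reads without injury and 0.538 after it. After injury its log2 ratio was -8.39 (-13.75 to -5.97), a value that rests on under 1 RiboTag read and depends on the pseudocount. Of the 10 most abundant transcripts of uninjured bulk RNA, 9 were lower in RiboTag RNA both without and with injury, and the 10 together held 9.72% of bulk and 1.41% of RiboTag reads without injury. Of the 8 transcripts at ranks 3 to 10 in uninjured RiboTag RNA, 6 were higher than in bulk RNA and 0 lower, at a median log2 ratio of 2.14. Both sets were chosen on abundance in a library that enters the ratio, which by itself favours these directions. Kit, strain and genotype differed between the assays, and the title's term ribosome association is used only for the question.

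The fourth comparison asked whether injury changed the RiboTag to bulk ratio of a transcript. Constant effects of kit and strain on a transcript cancel in this difference. Bulk RNA came from the whole ganglion and RiboTag RNA from sensory neurons. An injury change in other cells of the ganglion therefore does not cancel, and the difference is not a measure of ribosome association alone. Of 4905 transcripts, 129 had a higher and 177 a lower ratio after injury, with a median log2 change of -0.07. Totals without the dominant pair turned this split to 194 higher and 118 lower, with a median of 0.15. A pseudocount of 5 gave 85 higher and 34 lower (median 0.50), and no read minimum 227 higher and 209 lower (median 0.12). Among 3901 steady transcripts, 31 were higher and 66 lower. The transcripts with the largest changes were not steady. The ratio of ENSMUST00000079758.9 was at least 108-fold higher after injury, with 0 reads in injured bulk and uninjured RiboTag RNA. Its uninjured bulk columns ranged from 0 to 199 reads, and the call ended without column 1 or without column 3. The ratio of ENSMUST00000113918.8 was at least 54.3-fold lower, with 0 reads in uninjured bulk and injured RiboTag RNA. Its injured bulk columns ranged from 0 to 140.3 reads, and the call ended without column 3 or with a pseudocount of 5.

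The series title asks about ribosome association of injury-induced transcripts, which joins these comparisons. Of the 403 transcripts higher in bulk RNA, 65 also had 20 or more RiboTag reads. Their median log2 change was 1.54 in bulk and 0.21 in RiboTag RNA, and 12 were also higher in RiboTag RNA and 6 lower. The RiboTag median turned to -0.026 for the 21 transcripts that passed a 4-fold threshold and to -0.14 for the 36 that were higher in RiboTag than in bulk RNA without injury. Choosing those 36 on high uninjured RiboTag values by itself favours a fall there. The RiboTag median of the 65 lay above all 10000 matched random lists (95% range -0.39 to -0.00). The ratio change uses the same bulk libraries as the selection, so selection on high bulk values by itself lowers it. Their median ratio change was -1.48, below all matched lists (95% range -0.44 to 0.03), and 38 of the 65 were counted as lower in the ratio. The reverse selection gave the opposite sign. Of 55 transcripts higher in RiboTag RNA, 41 were measured in bulk RNA, where their median change was 0.44 with 12 also higher, and their median ratio change was 1.05.

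Steady transcripts that were higher in bulk RNA after injury were also higher in RiboTag RNA more often than independent lists would be. Of 13 steady transcripts that were higher in bulk RNA and measured in RiboTag RNA, 13 had a positive RiboTag change (0.33 to 4.24) and 8 were counted as higher. Independent lists would share 0.26. The median log2 change of the 13 was 1.79 in bulk RNA (1.01 to 7.10) and 1.51 in RiboTag RNA. Their median ratio change was -0.20 (bootstrap 95% range over transcripts -0.58 to 0.59), within the range of matched random lists (-0.61 to 0.23). Of the 13, 2 were counted as lower in the ratio. The 8 shared transcripts changed by 1.01 to 2.74 in bulk and by 1.46 to 4.24 in RiboTag RNA on the log2 scale. Among all 1594 transcripts measured in both assays, 9 were lower in both, where independent lists would share 3.79. Only 4 of the steady ones were lower in bulk RNA, too few to show shared falls.

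**Figure D3:**
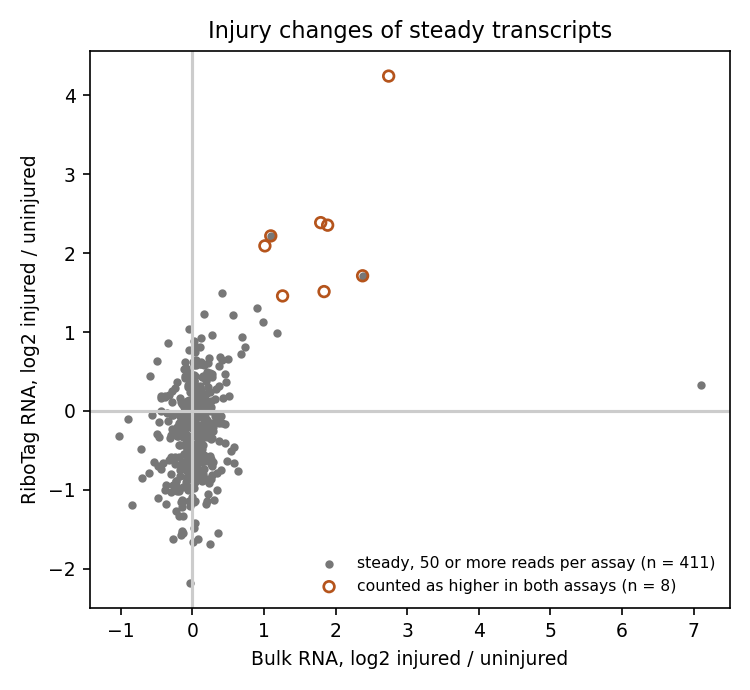
Log2 change after injury in bulk RNA (x axis) and RiboTag RNA (y axis), for 411 steady transcripts with 50 or more reads in each assay (grey points) and for the 8 steady transcripts counted as higher in both assays with 20 or more reads in each (orange circles). The 8 circled transcripts lie between 1.01 and 2.74 on the x axis and between 1.46 and 4.24 on the y axis.

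Over all transcripts with 50 or more reads in each assay, bulk and RiboTag changes correlated weakly. Pearson's r was 0.11 and Spearman's rho 0.21 across 507 transcripts, which are not independent replicates. With 200 or more reads in each assay (54 transcripts) r turned to -0.069. The changes did not repeat well between columns of the same libraries, where the mean r was 0.08 in bulk and 0.24 in RiboTag RNA. Across 411 steady transcripts r was 0.24 and rho 0.24. Without the steady transcript with the largest bulk change, r was 0.33. For the steady transcripts the mean correlations between columns were 0.80 in bulk and 0.67 in RiboTag RNA. Choosing transcripts whose columns agree by itself raises these column correlations, so they do not show how well the changes repeat.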

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

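Transcripts that moved in opposite directions in bulk and RiboTag RNA were looked for by a rule fixed before the data were examined, and the steadiness check beside them was chosen after the result was seen. Of 1594 transcripts measured in both assays, 8 were counted as changed in opposite directions, where independent lists would give 5.96, and 3 of the 8 were among those named by the rule. The difference between assays was not tested, since each group had 1 library. ENSMUST00000105616.10 had a RiboTag log2 change of 3.07 (2.46 to 3.77) and a bulk log2 change of -2.46 (-3.04 to -1.92), with injured RiboTag columns from 0 to 175.5 reads. ENSMUST00000113918.8 was at least 17.5-fold higher in bulk RNA and at least 3.11-fold lower in RiboTag RNA (log2 bound -1.64), with injured bulk columns from 0 to 140.3 reads. ENSMUST00000219317.2 had a RiboTag log2 change of 1.69 (0.35 to 2.93) and was at least 18.9-fold lower in bulk RNA, with uninjured bulk columns from 0 to 113.7 reads. None of the 3 was steady.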

How the results depend on the processing

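Alternatives added after the data were seen were the sum of columns, steady transcripts only, columns that do not overlap and totals without the dominant pair; the others were planned. For bulk injury (755 calls), a minimum of 50 reads gave 316, no minimum 1582, summed columns 2071, steady transcripts 138 and columns that do not overlap 241. For RiboTag injury (205) they gave 86 (15 higher, 71 lower), 441 (239 higher, 202 lower) and 1046 for the first 3, and a pseudocount of 5 gave 117 (60 higher, 57 lower). The uninjured ratio (3617) gave 1927 at 50 reads (398 higher, 1529 lower) and 7110 summed, the injured ratio (2202) 1157 at pseudocount 5 (404 higher, 753 lower) and 5130 summed, and the ratio change (306) 119 at pseudocount 5 (85 higher, 34 lower), 1396 summed and 97 among steady transcripts. Summing triples the reads, which narrows every interval and lets more transcripts pass the read minimum. It turned the split for bulk injury (1006 higher, 1065 lower) and for the ratio change (707 higher, 689 lower), and kept it for the other comparisons. The cause of the other shifts was not tested. Columns fitted as if replicates, at adjusted p of 0.05, gave 65 calls (edgeR) and 261 (DESeq2) for bulk injury, 161 (77 higher, 84 lower) and 134 (68, 66) for RiboTag injury, 3165 (1416, 1749) and 3434 (1398, 2036) for the uninjured ratio, 1974 (723, 1251) and 2313 (711, 1602) for the injured ratio, and 110 (27, 83) and 174 (58, 116) for the ratio change. The columns share only a number, and with it as a replicate block edgeR gave 1, 7 (3 higher, 4 lower), 2250 (1152, 1098), 820 (407, 413) and 45 (9, 36) calls in the order of the comparisons. Leaving out each column gave 887 to 918, 242 to 267, 3642 to 3663, 2294 to 2312 and 385 to 430. The RiboTag median of bulk-induced transcripts (0.21) reversed to -0.026 at 4-fold and to -0.14 for transcripts higher in RiboTag than in bulk RNA, and was 0.10 with TMM, 0.29 at 50 reads, 1.51 for steady transcripts and 0.43 without the pair. Choosing transcripts higher in RiboTag than in bulk RNA without injury by itself favours a fall in RiboTag RNA. The reverse selection in RiboTag RNA gave a bulk median of 0.44, a different quantity. The correlation (0.11) reversed to -0.069 at 200 reads (54 transcripts) and was 0.24 for steady transcripts. Of 139 alternatives that could move the 20 named values, 134 kept direction and threshold and 5, all of the ratio change, lost the threshold. These values were chosen as the extremes of the same data, far past 2-fold, so keeping the threshold says little about how firm they are. ENSMUST00000047104.15 had no value without column 3, which left under 3 reads in both libraries. The deposited TPM gave nearly the same counts by construction. Gene sums, totals without mitochondrial genes and gene lists were not run for lack of gene names. At the depth of injured RiboTag RNA, 0 reads allow 37.8 on the TPM scale.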

Other observations

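All tests in this part were chosen after the data were seen, except TMM scaling and the edgeR fit, which were planned, and the thinning of the uninjured RiboTag library, whose predicted outcome was written down before it was run. Each assay held transcripts that the other did not show. Of 7739 transcripts with 20 or more reads over both bulk libraries, 769 (9.94%) had 0 reads in both RiboTag libraries, and of 2086 with 100 or more bulk reads, 138 (6.62%) did. Of 1866 transcripts with 20 or more reads over both RiboTag libraries, 70 (3.75%) had 0 reads in both bulk libraries, and of 233 with 100 or more, 6 (2.58%) did. The shares are not comparable between assays, since the bulk libraries were deeper (592935 and 529332 reads against 207597 and 79334). The pair also took much of the RiboTag depth. How many of the values of 0 come from lower depth was not tested. Among 1055 transcripts with 20 or more reads in each uninjured library, the highest log2 ratio of RiboTag to bulk RNA outside the dominant pair was 4.66, against 10.68 for the pair summed. Transcripts rare or at 0 in bulk RNA are left out of that set, among them ENSMUST00000154078.3 at no less than 617-fold.

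The 10 most abundant transcripts of uninjured bulk RNA held 9.72% of bulk reads without injury and 8.74% after it. In RiboTag RNA they held 1.41% and 0.892%. None of the 10 was counted as changed by injury in either assay. The 8 transcripts at ranks 3 to 10 of uninjured RiboTag RNA held 6.68% of RiboTag reads without injury and 4.12% after it, at a median log2 change of -0.70 with 1 counted as lower. In bulk RNA their median log2 change was 0.09. Choosing transcripts on abundance in the uninjured RiboTag library by itself favours a fall there.

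The number of bulk transcripts called after injury may owe much to reads assigned to another transcript close by in the list. Of the 755 calls, 58.5% (442) had a transcript within 10 places that moved the opposite way by a like amount, against 12.2% (92) at places displaced by 1000. The remaining 313 calls had no such neighbour. The search looked only for a single transcript within 10 places. It cannot tell whether reads spread over several transcripts, or assigned farther off, account for these calls. For calls with an opposite neighbour, a real shift between nearby transcripts would leave the same pattern, and the search cannot tell it from read assignment. ENSMUST00000082424.12 and ENSMUST00000159216.10, which moved in opposite ways, were both steady in bulk RNA. Among steady transcripts 138 calls were left, of which 23.9% had an opposite neighbour against 19.6% at displaced places. Whether these 138 reflect injury or a difference between animals or libraries cannot be told apart, since each group had 1 library.

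Lower calls outnumbered higher calls in RiboTag RNA after injury, and whether the larger share of reads taken by the dominant pair accounts for this stays open. With the pair left out of the totals 51.2% of calls were higher, but this shifts every transcript alike and so cannot decide. TMM scaling gave 46 higher and 202 lower, but its factors were computed over both assays together, so it cannot decide either. The edgeR fit, with TMM within the RiboTag columns and no fold threshold, gave 77 higher and 84 lower. Lower total depth of the injured library did not by itself account for it. With the uninjured library thinned to the same total, 29.4% of calls were higher in the mean of 20 draws (24.4% to 34.2%), where 40% to 60% had been predicted if depth were the reason. Thinning left the share of the pair in place, with a log2 change of -0.22 for all other reads together. This by itself favours lower calls, so the thinning cannot tell depth from the pair. Why the pair takes a larger share after injury was not tested, and injury, immunoprecipitation and PCR all remain open.

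The RiboTag to bulk ratio fell for transcripts that were higher in bulk RNA, and part of this fall may come from choosing transcripts whose reads were assigned differently between the bulk libraries. Among 87 transcripts chosen on column 1 alone, the median bulk log2 change with counts of 0 set to 3 reads was 3.16 in that column and 0.51 in the other columns. With 0.5 read added instead, the other columns gave medians of 0.50 in bulk and 0.19 in RiboTag RNA. For the 22 steady ones these were 0.95 and 0.72. Steady transcripts were chosen for columns that agree, so their other bulk columns were not independent of column 1. This by itself keeps the bulk median high, so these medians cannot decide whether a smaller RiboTag change remained. All these columns come from the same libraries. Among the 13 steady transcripts with enough RiboTag reads the median ratio change was -0.20, within the range of matched random lists. A lower ribosome association of injury-induced transcripts stays open. Each group had 1 library, and a change in ganglion cells other than sensory neurons would also move the ratio. The bootstrap range of that median was -0.58 to 0.59. It covers only the spread over transcripts, which may share genes, and not the spread between animals.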
